A study of Homo sapiens with 44 samples.

How the data were processed

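The series holds 44 samples: 14 RNA sequencing libraries and 30 chromatin immunoprecipitation libraries for EZH2, RelA, RelB and NFKB2 with input controls. The 30 chromatin libraries were not analysed here. The RNA libraries fall into 7 groups of 2 biological replicates, taken from the labels: control siRNA, siRelA and siRelB in MDA-MB-231 cells in the first experiment, and control siRNA and siEZH2 in MDA-MB-231 and in SUM149 cells in the second. The siRNA dose was 20 nM and the time after transfection 48 h. The siRNA sequences were not given in the sources used here.

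For the first experiment the authors deposited a table of raw read counts per Ensembl gene. Its values are whole numbers in 58735 genes, and the deposited counts sum to 18.6 to 24.4 M reads per library. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and genome build hg19. For the second experiment the authors deposited variance-stabilised values on a log2-like scale, already normalised between libraries, for 27315 gene symbols. The notes name cutadapt, STAR 2.5.2b, Salmon, DESeq2 and hg19. The role of each tool, the annotation release, the strand setting and the transformation settings are not given in the sources used here. The variance-stabilised table has a lowest value of 7.12, which 8226 symbols show in all 8 libraries. Differences on this scale understate the fold change of genes with few reads. Positions are from GENCODE v44 on GRCh38 and were not converted to or from hg19. Of the identifiers with counts, 58207 matched that annotation, and of the symbols 26178 matched, 1089 of them through an older symbol. The sequences of EIF3C and EIF3CL and of U2AF1 and its copy are nearly identical, so their reads can be assigned to either copy.

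Counts were fitted with the quasi-likelihood method of edgeR 4.0.16 on all 6 libraries of the first experiment, with TMM normalisation, the default filter on low counts and a term for group. This tested 15930 genes with 3 residual degrees of freedom and a biological coefficient of variation of 10.1%. Variance-stabilised values were fitted with limma 3.58.1 (lmFit, and eBayes with a variance trend) on all 8 libraries of the second experiment, with a term for group. The fit kept 12356 genes that lay at least 1 above the lowest value in at least 2 libraries, and left 4 residual degrees of freedom. All p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at adjusted p under 0.05. R was version 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

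The comparisons were siRelA and siRelB against their control and against each other, siEZH2 against its control in each line, the difference of the siEZH2 effects between the lines (the interaction term) and the lines' controls. Shared calls were counted per direction beside the number that independent calls would give and tested by Fisher's exact test, two-sided. For siRelA and siRelB, which share controls, 100 pairs of unchanged groups were simulated from the control means. Calls common to 3 or 4 knockdowns were set beside the number expected if siEZH2 calls were independent of those siRelA and siRelB share, a test added after seeing the data. The experiments were joined on 11630 genes. Controls were not split, since each part would hold 1 library.

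A set of 22 gene lists with 489 entries was fixed before the data were examined: NF-kB subunits and kinases, NF-kB feedback targets, cytokines and chemokines, PRC2 members, genes described as repressed by PRC2, G1/S genes, G2/M genes, type I interferon response, antigen presentation, mesenchymal genes, epithelial genes, proteases and matrix remodelling, survival genes, pro-apoptotic genes, stress and amino acid response, cholesterol synthesis, hypoxia and glycolysis, Notch pathway, fibroblast markers, haematopoietic markers, mitochondrial mRNAs and replication-dependent histone mRNAs. Lists with at least 5 tested members were tested with camera of limma, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera was repeated with a correlation estimated for each list, and no list call held with it in any of the 7 comparisons. This setting also tests on the 3 or 4 residual degrees of freedom of the fits, so few lists can pass whatever their correlation. For NF-kB subunits and kinases under siRelA the estimated correlation was -0.0750, under the preset 0.01. Their camera adjusted p still rose from 2.0e-08 to 0.0860. A call lost in this way therefore does not show that correlated genes had made it. Camera was also run with the replicate block and on the ranked test statistics (preranked), which changed the calls of some lists.

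Genes were named by a rule written before the data were examined. It took the NF-kB subunits and EZH2, the 5 protein-coding genes with the largest called rise and the 5 with the largest called fall (4 and 4 for comparisons other than knockdown against control), with a mean of at least 1 on the log2 CPM scale or 3 above the lowest value and no overlap of the groups, and from each list up to 4 members with the smallest adjusted p. Genes named for shared or opposite calls, and sites in 3′ UTRs, were chosen after the values were seen. A few genes that the rule takes are not reported here.

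The presence of each 7-base word in the 3′ UTR of the canonical transcript was related to the change by regression, after the length and GC content of the 3′ UTR, for words in at least 20 genes. The z scores were set beside those of 100 shuffles of the genes. The search covered 12810 genes of the first experiment and 11668 of the second; 3120 and 421 without an annotated 3′ UTR were not searched.

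The steps were tested on simulated data with known changes. For genes changed 2-fold the share found was 56.7% for siRelA (15094 genes), 73.1% for siRelB (15121), 91.0% for siEZH2 in MDA-MB-231 (12149) and 94.0% in SUM149 (12132). The share of false calls was 8.59%, 6.80%, 2.76% and 7.65%, against a nominal share of 0.05. Camera found 20 of 20 planted lists and called 2 of 380 unchanged lists. Genes were drawn independently of each other there, so this gives no rate of false calls for lists of correlated genes. A planted 7-base word was found in all 4 comparisons. Variance-stabilised values were inverted to counts, and 74.5% to 81.0% of the recovered values up to 20 reads lay within 0.05 of a whole number. The recovered totals were 17.4 to 38.1 M reads per library.

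The alternatives tried were DESeq2 1.42.0 size factors and its Wald test, robust dispersion, no filter and stricter filters on low values, fits with the groups compared only, no variance trend, quantile normalisation, median-centring, a minimum change of 1.5-fold, adjusted p under 0.1 for shared calls, the replicate number as a block, and leaving out each library in turn. Fits to recovered counts, a crossed replicate block in SUM149 and gene lists without the targeted genes were added after seeing the data.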

Results

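Gene expression was measured by RNA sequencing in 14 libraries from human triple-negative breast cancer cells, which lack oestrogen receptor, progesterone receptor and HER2. The lines were MDA-MB-231 and SUM149, the latter from an inflammatory breast cancer. Cells were transfected with 20 nM small interfering RNA (siRNA) and collected after 48 h. The first experiment used MDA-MB-231 cells with a control siRNA, siRelA or siRelB, and the second used both lines with a control siRNA or siEZH2. Each of the 7 groups held a biological duplicate. RELA and RELB are subunits of the transcription factor NF-kB, of its canonical and non-canonical arm, and EZH2 is the histone methyltransferase of Polycomb repressive complex 2 (PRC2). The count table of the first experiment held 24.0 and 23.2 M reads for the control libraries, 24.4 and 21.5 M for siRelA and 18.6 and 19.7 M for siRelB. The second experiment was deposited as variance-stabilised values on a log2-like scale, without read totals. Changes are given on the log2 scale with the standard error of the fitted model, from 2 libraries per group.

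The targeted genes were read first in every library. RELA, on chromosome 11 at 65653599 to 65663090 of GRCh38, had 3562 and 3391 counts in the control libraries and 265 and 275 in the siRelA libraries. That was 152 ± 2.75 against 11.6 ± 1.26 CPM, counts scaled to library size (SD, n = 2), a 13.1-fold difference, and the change was -3.71 ± 0.11 (edgeR adjusted p = 1.4e-12). RELB, on chromosome 19 at 45001461 to 45038192, had 923 and 916 counts in the controls and 90 and 107 under siRelB, a 7.87-fold difference (-2.98 ± 0.16, edgeR adjusted p = 6.4e-09). RELB also fell under siRelA, to 377 and 295 counts, a 2.79-fold difference (-1.48 ± 0.14, edgeR adjusted p = 1.6e-06). RELA did not pass the test under siRelB (3117 and 3114 counts). EZH2, on chromosome 7 at 148807257 to 148884321, passed in neither, with 2606 and 2417 counts in the controls, 2655 and 2553 under siRelA and 2301 and 2418 under siRelB. In the second experiment EZH2 fell by 2.52 ± 0.07 under siEZH2 in MDA-MB-231 (limma adjusted p = 5.5e-11) and by 2.00 ± 0.07 in SUM149 (limma adjusted p = 4.8e-10). Counts recovered from the variance-stabilised values put EZH2 at 3022 and 3020 in the MDA-MB-231 controls and 368 and 298 under siEZH2, 9.08-fold lower, and at 2563 and 2746 against 442 and 517 in SUM149, 5.54-fold lower.

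**Figure D1:**
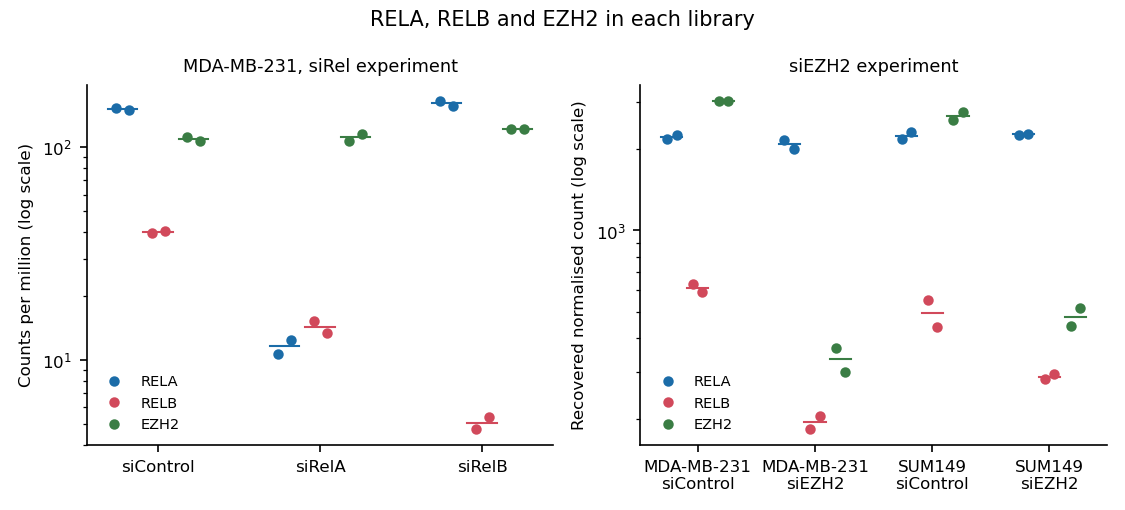
Levels of RELA, RELB and EZH2 in each library, on log axes: CPM in the first experiment (left) and normalised counts recovered from the variance-stabilised values in the second (right), with points for libraries and bars for group means. RELB was lower under siRelB, siRelA and siEZH2 than in the respective controls.

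The comparison of siRelA with its control asks which transcripts depend on RelA in MDA-MB-231. Known NF-kB target genes fell: of 30 tested feedback genes 17 fell and 0 rose (0 rose and 19 fell adjusted over the list alone). Among them were BIRC3 (-2.55 ± 0.15), an inhibitor of apoptosis, NFKBIA (-1.21 ± 0.10), which encodes the inhibitor IkB-alpha, PTX3 (-1.04 ± 0.12) and CD83 (-1.22 ± 0.14). Type I interferon response genes rose, with 20 of 37 up and 1 down (26 up and 1 down adjusted over the list alone). Examples were IFIT3 (1.07 ± 0.09), DDX60 (1.34 ± 0.13), HERC6 (1.04 ± 0.12) and IFIH1 (1.33 ± 0.18), a sensor of double-stranded RNA. Genes of hypoxia and glycolysis fell in 14 of 22 cases and rose in 0 (15 and 0 adjusted over the list alone), including LDHA, which fell by 2.00 ± 0.08, the glucose transporter SLC2A3 (-2.31 ± 0.12), HK2 (-1.05 ± 0.09) and PFKFB3 (-1.13 ± 0.10).

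Against the other genes, camera called 6 lists under siRelA. Feedback targets were lower (adjusted p = 7.5e-12), and so were hypoxia and glycolysis (adjusted p = 9.2e-17), while the interferon response was higher (adjusted p = 9.0e-10). With an estimated correlation these became adjusted p = 0.0944, adjusted p = 0.0860 and adjusted p = 0.116. NF-kB subunits and kinases were lower (1 of 14 rose and 7 fell, 2 and 7 adjusted over the list alone, camera adjusted p = 2.0e-08, adjusted p = 0.0860 with an estimated correlation). This list holds RELA and RELB. Without RELA 6 of 13 fell (camera adjusted p = 0.00942, adjusted p = 0.202 with an estimated correlation). Without both 5 of 12 fell and the list did not pass (camera adjusted p = 0.0860). In that list NFKB2, the precursor of p52, changed by -0.65 ± 0.10, NFKB1 by -0.42 ± 0.11 and NFKBIB by -0.81 ± 0.14, while REL stood at -0.04 ± 0.26 and did not pass. NFKB1 lost its call without control replicate 1 (-0.45), control replicate 2 (-0.40) or siRelA replicate 2 (-0.36). Cytokines and chemokines were lower too: 1 of 21 rose and 9 fell (1 and 10 adjusted over the list alone, camera adjusted p = 0.00027, adjusted p = 0.168 with an estimated correlation). They included CXCL8 (-2.37 ± 0.28), IL11 (-1.61 ± 0.15), LIF (-0.77 ± 0.10) and CSF2 (-2.40 ± 0.35), the granulocyte-macrophage growth factor. Of 6 survival genes XIAP rose (0.61 ± 0.11) and MCL1 fell (-1.68 ± 0.08), with 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.0341, adjusted p = 0.332 with an estimated correlation). The 3′ UTR of MCL1 holds GCCTAGT, the 7-base word most tied to falls under siRelA, so its fall need not follow from the loss of RelA.

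No other list passed camera under siRelA, though single members changed. Of the G1/S genes 6 of 29 rose and 10 fell (6 and 14 adjusted over the list alone), with E2F2 at 1.17 ± 0.18, RRM2 at 0.76 ± 0.10 and MCM2 at -0.52 ± 0.09, whereas among 28 G2/M genes 0 rose and 1 fell (UBE2C, -0.43 ± 0.11, not called without control replicate 1 at -0.29 or siRelA replicate 1 at -0.31). AURKB (-0.34 ± 0.12, adjusted p = 0.0522) passed in all 7 alternatives that kept every library. MKI67 (0.26 ± 0.09) and KIF11 (0.27 ± 0.09) did not pass, but were called up in 5 and 2 of them. Proteases and matrix genes went both ways (4 of 24 up, 4 down), from the urokinase PLAU (-2.45 ± 0.10) to the sheddase ADAM17 (1.09 ± 0.12). Mesenchymal genes were split alike (4 of 23 up, 4 down), with the cytoskeletal linker MSN at -1.85 ± 0.07 and the collagen COL5A1 at 1.09 ± 0.08. Epithelial genes rose in 7 of 19 cases and fell in 2, for example the plakophilin PKP3 (0.79 ± 0.12) and CLDN7 (1.07 ± 0.21). PRC2 members (3 of 13 up, 2 down) included JARID2 (0.88 ± 0.10) and EPOP (-1.14 ± 0.18), both PRC2 accessory proteins. Genes described as repressed by PRC2 (1 of 18 up, 6 down) included DKK1 (-0.75 ± 0.11) and RAP1GAP (1.73 ± 0.26). Pro-apoptotic genes (2 of 19 up, 2 down) included PMAIP1 (-0.87 ± 0.11) and BMF (1.98 ± 0.26). Antigen presentation (2 of 16 up, 1 down) held ERAP1 (1.00 ± 0.09), and the Notch list (2 of 15 up, 3 down) held RBPJ (-0.75 ± 0.09). Stress genes (1 of 22 up, 6 down), cholesterol genes (2 of 22 up, 6 down), fibroblast markers (2 of 5 up, 0 down) and histone mRNAs (0 of 11 up, 2 down) completed the set. The 13 mitochondrial mRNAs, which made up 3.30% to 4.21% of the reads of each library, did not pass edgeR, with MT-ATP8 at 0.34 ± 0.14 (adjusted p = 0.11), nor did the 2 haematopoietic markers tested (CSF1R, 0.51 ± 0.18). Median, mean and test differed in sign for PRC2 members, mesenchymal, pro-apoptotic and Notch genes.

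Of all 15930 genes tested, edgeR called 1405 up and 1626 down under siRelA, and 729 and 612 of these changed at least 1.5-fold. The largest rises by the stated rule were PRLR, the prolactin receptor (2.78 ± 0.20, adjusted p = 7.8e-08), GREB1 (2.35 ± 0.41), RAB17 (2.29 ± 0.43), TMEM37 (2.25 ± 0.38) and AGR2 (2.10 ± 0.20). Below RELA, the largest falls were PLA2G12A (-2.96 ± 0.22, adjusted p = 8.7e-08), the cadherin FAT3 (-2.83 ± 0.34), TMX3 (-2.62 ± 0.13) and BIRC3. The total of 3031 calls dropped to 1624 without control replicate 1 and to 1786 without control replicate 2.

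The comparison of siRelB with its control asks the same of RelB. NF-kB feedback genes went both ways, with 4 of 30 up and 3 down (5 and 3 adjusted over the list alone): PTX3 (1.17 ± 0.11) and NFKBIE (0.60 ± 0.10) rose, while the syndecan SDC4 (-0.69 ± 0.09) and TNIP1 (-0.49 ± 0.08) fell. Among cytokines 4 of 21 rose and 4 fell (5 and 5 adjusted over the list alone), with the macrophage growth factor CSF1 at -1.53 ± 0.08, LIF at -0.56 ± 0.10, CSF2 at -1.25 ± 0.33 and IL11 at 0.78 ± 0.14. Of the NF-kB subunits and kinases 3 of 14 rose and 2 fell, RELB among the latter (3 and 3 adjusted over the list alone). NFKB2 rose by 0.50 ± 0.10 and MAP3K14, the kinase of the non-canonical arm, by 1.13 ± 0.09, while NFKB1 stood at -0.32 ± 0.11 (edgeR adjusted p = 0.053). Without control replicate 2 NFKB2 was no longer called (0.38), and CSF2 was not called without control replicate 1 (-1.29), control replicate 2 (-1.22) or siRelB replicate 1 (-0.99).

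Camera called 3 lists under siRelB. Hypoxia and glycolysis genes were lower, with 0 of 22 up and 7 down (0 and 7 adjusted over the list alone, camera adjusted p = 0.00724, adjusted p = 0.601 with an estimated correlation). They included NDRG1 (-1.17 ± 0.09), the angiogenic factor VEGFA (-0.87 ± 0.09), PDK1 (-0.78 ± 0.15) and SLC2A3 (-0.63 ± 0.11). Genes described as repressed by PRC2 were lower as well, with 1 of 18 up and 5 down over all genes and 1 and 5 adjusted over the list alone (camera adjusted p = 0.0229, adjusted p = 0.601 with an estimated correlation). These held the protease inhibitors TIMP2 (-1.03 ± 0.08) and TIMP3 (-0.73 ± 0.08), SLIT2 (-1.28 ± 0.16) and PPARG (-0.90 ± 0.12). Antigen presentation was higher, with 3 of 16 up and 1 down (6 and 1 adjusted over the list alone, camera adjusted p = 0.0201, adjusted p = 0.601 with an estimated correlation), including ERAP1 (1.01 ± 0.09) and TAP1 (0.44 ± 0.09).

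The remaining lists did not pass camera under siRelB. Notch genes fell in 4 of 15 cases and rose in 0, among them the ligand JAG1 (-0.77 ± 0.09), MAML2 (-1.08 ± 0.13), NOTCH2 (-0.72 ± 0.09) and NOTCH1 (-0.51 ± 0.09). Epithelial genes fell in 6 of 19 cases and rose in 0, for example CLDN4 (-0.55 ± 0.09) and DSP (-0.48 ± 0.09). Mesenchymal genes rose in 2 of 23 cases and fell in 7, for example CCN1 (-0.80 ± 0.09) and SNAI2 (-0.63 ± 0.11). The G1/S list (5 of 29 up, 4 down) included RRM2 (1.14 ± 0.10) and CCNE2 (1.36 ± 0.15). Interferon genes rose in 2 of 37 cases and fell in 1, and survival genes included MCL1 (0.51 ± 0.08). Median, mean and test differed in sign for cytokines, G2/M, interferon, survival, mitochondrial, Notch and histone genes, none of which passed.

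Across all genes edgeR called 1187 up and 1726 down under siRelB, 507 and 817 of them at least 1.5-fold. The largest rises by the same rule were CARNMT1 (1.86 ± 0.15, adjusted p = 2.7e-07), the phosphodiesterase PDE4B (1.78 ± 0.32), CTXN1 (1.77 ± 0.25), CHORDC1 (1.76 ± 0.10) and SPEF2 (1.76 ± 0.53). Below RELB, the largest falls were ASB2 (-2.92 ± 0.40), ANK2 (-2.67 ± 0.19), the integrin subunit ITGB8 (-2.65 ± 0.56) and GALNT12 (-2.45 ± 0.39). SPEF2 lost its call without control replicate 1 (1.98), control replicate 2 (1.55) or siRelB replicate 1 (0.96). The total of 2913 calls dropped to 1754 without control replicate 1 and to 1520 without control replicate 2.

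Contrasting siRelA directly with siRelB asks where the subunits differ. NF-kB feedback genes were lower under siRelA in 15 of 30 cases and higher in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 1.1e-09, adjusted p = 0.209 with an estimated correlation), and CXCL8 differed by -3.20 ± 0.27 (edgeR adjusted p = 2.9e-07). Interferon genes were higher under siRelA in 19 of 37 cases and lower in 1 (20 and 1 adjusted over the list alone, camera adjusted p = 3.6e-06, adjusted p = 0.231 with an estimated correlation). Epithelial genes were higher in 10 of 19 cases and lower in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.00200, adjusted p = 0.333 with an estimated correlation). Hypoxia and glycolysis genes were lower in 10 of 22 cases and higher in 4 (11 and 4 adjusted over the list alone, camera adjusted p = 4.9e-05, adjusted p = 0.231 with an estimated correlation). Lower under siRelA were also subunits and kinases (camera adjusted p = 3.2e-05, adjusted p = 0.209 with an estimated correlation, and 0.0139 and 0.281 without RELA and RELB), cytokines (camera adjusted p = 0.0183, adjusted p = 0.333 with an estimated correlation), stress genes (camera adjusted p = 0.0368, adjusted p = 0.350 with an estimated correlation) and survival genes (camera adjusted p = 0.0368, adjusted p = 0.333 with an estimated correlation). For survival genes the median was 0.04 and the mean -0.27. In all, 2541 genes were higher and 2227 lower under siRelA, and by the stated rule the genes highest under siRelA were ITGB8 (3.61 ± 0.54), the synaptotagmin SYT2 (3.58 ± 0.39), MEF2C (3.15 ± 0.46) and ZNF704 (3.09 ± 0.33). RELA (-3.80 ± 0.11), U2AF1, CXCL8 and FAM167A (-2.91 ± 0.28) were the lowest. U2AF1 differed by -3.33 ± 0.73, but its counts were 22 and 30 under siRelA and 392 and 38 under siRelB, its reads can fall on a near-identical paralog, and its adjusted p was 0.219 with robust dispersion. Without siRelB replicate 1 the difference was -0.77 and did not pass.

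siRelA and siRelB shared 369 genes that rose in both and 392 that fell in both, 761 in all, against 105 and 176 for independent calls; 213 were called in opposite directions, against 273. MED20 (1.28 and 1.38), CARNMT1 (2.08 and 1.86) and NECAP1 (1.31 and 1.52) rose in both, and RELB, ANKRD52 (-1.18 and -1.20) and STAC (-1.43 and -1.55) fell in both. Both comparisons used the same 2 control libraries. Across genes, which are not independent replicates, the correlation of the changes was 0.263, against 0.491 in simulated unchanged groups with shared controls, and the covariance was 0.113 against 0.0633. These simulated pairs shared a median of 0 calls and at most 1, against 761. This is a reference for unchanged groups and not for groups that both changed. It also leaves out silencing of genes by the control siRNA, which would raise the same genes in both comparisons. The words TGACTAA (z = 8.18 under siRelA and 5.78 under siRelB) and GACTAAA (7.23 and 5.99) had the highest z scores in both. Such silencing was not tested, so the shared calls need not be effects common to RelA and RelB.

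Knockdown of EZH2 in MDA-MB-231 asks which transcripts depend on EZH2, and whether these include NF-kB genes. RELB fell by 1.02 ± 0.08 (limma adjusted p = 1.7e-07), with recovered counts of 632 and 589 in the controls and 184 and 206 under siEZH2, 3.13-fold lower. NFKB1 changed by -0.63 ± 0.05 and NFKB2 by -0.30 ± 0.07, while RELA (-0.08 ± 0.06) and REL (0.13 ± 0.07) did not pass. Subunits and kinases rose in 1 of 14 cases and fell in 7 (1 and 7 adjusted over the list alone) without passing camera (adjusted p = 0.100), though on recovered counts the list passed (adjusted p = 0.0355). With an estimated correlation its adjusted p was 0.333. Feedback genes went both ways, with 10 of 29 up and 8 down, for example PTX3 (0.94 ± 0.06) and the deubiquitinase CYLD (0.50 ± 0.05) against BIRC2 (-0.74 ± 0.06) and BIRC3 (-0.39 ± 0.05). The RELB 3′ UTR carries the sequence CCCAATAA, on chromosome 19 at 45038168 to 45038175 in exon 12, and the same 8 bases stand in the coding sequence of the EZH2 mRNA, on chromosome 7 at 148818020 to 148818027 in exon 10.

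Interferon genes rose in MDA-MB-231 under siEZH2, 30 of 36 up and 1 down (30 and 1 adjusted over the list alone, camera adjusted p = 6.4e-09, adjusted p = 0.189 with an estimated correlation). SAMD9L changed by 1.93 ± 0.06, IFIT2 by 1.90 ± 0.06, IFIT3 by 1.26 ± 0.08 and DDX60 by 0.95 ± 0.06. Antigen presentation rose alongside, 14 of 16 up and 0 down (14 and 0 adjusted over the list alone, camera adjusted p = 0.000198, adjusted p = 0.333 with an estimated correlation), with HLA-E at 0.97 ± 0.06, ERAP2 at 0.72 ± 0.06 and the peptide transporter TAP1 at 0.64 ± 0.06. Proteases and matrix genes rose in 17 of 25 cases and fell in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.333 with an estimated correlation), led by LOX (2.16 ± 0.08), which crosslinks collagen, TNC (1.69 ± 0.06), ADAM19 (1.12 ± 0.06) and ADAM17 (1.03 ± 0.06). G1/S genes fell in 22 of 29 cases and rose in 1 (22 and 1 adjusted over the list alone, camera adjusted p = 3.0e-06, adjusted p = 0.333 with an estimated correlation), including cyclin D1 CCND1 (-1.10 ± 0.05), MCM3 (-1.10 ± 0.06), POLA1 (-1.09 ± 0.06) and CCNE1 (-0.75 ± 0.07).

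Mesenchymal genes were higher under siEZH2 in MDA-MB-231 (14 of 23 up, 4 down, 15 and 4 adjusted over the list alone, camera adjusted p = 0.0352, adjusted p = 0.333 with an estimated correlation). ZEB1, a repressor of epithelial genes, rose by 1.24 ± 0.05 and COL5A1 by 1.36 ± 0.07, while THBS1 stood at -1.43 ± 0.09. Epithelial genes were lower (3 of 20 up, 13 down, 4 and 13 adjusted over the list alone, camera adjusted p = 0.0237, adjusted p = 0.385 with an estimated correlation), for example EPCAM (-1.03 ± 0.07), ESRP2 (-0.88 ± 0.07) and DSP (-0.73 ± 0.07). Cytokines were lower (1 of 22 up, 10 down, 1 and 10 adjusted over the list alone, camera adjusted p = 0.0397, adjusted p = 0.480 with an estimated correlation), with IL24 at -1.64 ± 0.06, IL6 at -0.92 ± 0.07 and CSF1 at 0.77 ± 0.06. Histone mRNAs were lower (0 of 24 up, 13 down, 0 and 11 adjusted over the list alone, camera adjusted p = 0.0237, adjusted p = 0.526 with an estimated correlation), for example HIST1H4C (-0.51 ± 0.10). Genes described as repressed by PRC2 did not pass camera (6 of 25 up, 6 down), with TIMP3 at 1.10 ± 0.07, the cell cycle inhibitor CDKN1C at 0.60 ± 0.07 and DKK1 at -0.97 ± 0.06. PRC2 members fell in 8 of 13 cases, EZH2 included, and rose in 2 (camera adjusted p = 0.0514, or 0.142 with 7 of 12 down without EZH2), among them EED (-0.33 ± 0.06) and SUZ12 (-0.36 ± 0.07), the core partners of EZH2. Of the 18 pro-apoptotic genes 8 rose and 2 fell, with the apoptosome scaffold APAF1 at 1.80 ± 0.07. The remaining lists did not pass: G2/M (8 of 28 up, 6 down), survival (3 of 6 up, 3 down), stress (5 of 22 up, 10 down), cholesterol (3 of 22 up, 9 down), hypoxia (8 of 20 up, 5 down; the mean, -0.03, was opposite in sign to the median, 0.07) and Notch (3 of 11 up, 4 down; the mean, 0.03, was opposite in sign to the test). Fibroblast markers rose in 2 of 5 cases (COL1A2, 1.05 ± 0.05) and the 3 haematopoietic markers tested rose (CD68, 0.97 ± 0.09). Some of these calls depended on the method. With the replicate block PRC2 members (adjusted p = 0.0413, adjusted p = 0.333 with an estimated correlation) and cholesterol genes (adjusted p = 0.0483, adjusted p = 0.480 with an estimated correlation) passed. On recovered counts PRC2 members (adjusted p = 0.00530), pro-apoptotic genes (adjusted p = 0.0226) and stress genes (adjusted p = 0.00743) passed. With an estimated correlation these had adjusted p = 0.333, adjusted p = 0.385 and adjusted p = 0.385. In preranked camera these 3 and fibroblast markers (adjusted p = 0.0452, adjusted p = 0.395 with an estimated correlation) passed, while histone mRNAs did not (adjusted p = 0.0770).

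Limma called 3636 genes up and 3354 down of 12356 in MDA-MB-231, and 740 and 408 of these moved by at least 1.5-fold on the deposited scale. The surplus of rises turned with median centring (3184 up, 3910 down), quantile normalisation (3322, 3792) and the stricter low-value filter (2295, 2525). Among genes with a mean at least 3 above the lowest value, which leaves out LOX, the largest rises were CDH11, a mesenchymal cadherin (2.38 ± 0.07, adjusted p = 5.8e-11), SFXN1 (2.16 ± 0.05), LRRC58 (2.13 ± 0.07), MGAT2 (2.00 ± 0.06) and CDKN3 (2.00 ± 0.07). After EZH2, the largest falls among them were CNN2 (-2.03 ± 0.06, adjusted p = 5.5e-11), the cystine transporter SLC7A11, which fell by 2.00 ± 0.05, ADM (-1.78 ± 0.09) and CNOT6 (-1.65 ± 0.06).

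The same knockdown in SUM149 asks whether this holds in a second line. RELB fell by 0.50 ± 0.08 (limma adjusted p = 0.00011), 1.73-fold lower in recovered counts, from 553 and 440 to 281 and 293. NFKB1 changed by -0.28 ± 0.05 and NFKB2, at -0.10 ± 0.07, did not pass. Proteases and matrix genes rose in 23 of 25 cases and fell in 1 (24 and 1 adjusted over the list alone, camera adjusted p = 2.9e-11, adjusted p = 0.171 with an estimated correlation), including MMP9 (1.55 ± 0.07) and PLAU (1.38 ± 0.06). Mesenchymal genes rose in 17 of 23 cases and fell in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 4.1e-05, adjusted p = 0.164 with an estimated correlation), including COL5A1 (2.03 ± 0.07), ITGA5 (1.48 ± 0.07) and SNAI2 (1.06 ± 0.05). Interferon genes rose in 25 of 36 cases and fell in 0 (25 and 0 adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.164 with an estimated correlation), with PARP9 at 0.87 ± 0.07, and antigen presentation in 15 of 16 with 0 down (15 and 0 adjusted over the list alone, camera adjusted p = 0.000125, adjusted p = 0.238 with an estimated correlation), with ERAP2 at 1.63 ± 0.06 and NLRC5 at 0.97 ± 0.08.

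Lower in SUM149 under siEZH2 were cholesterol synthesis (2 of 22 up, 17 down, 2 and 17 adjusted over the list alone, camera adjusted p = 0.000167, adjusted p = 0.238 with an estimated correlation), with INSIG1 at -0.93 ± 0.06 and DHCR7 at -0.85 ± 0.06. Stress and amino acid response genes were lower (2 of 22 up, 13 down, 2 and 13 adjusted over the list alone, camera adjusted p = 0.000632, adjusted p = 0.164 with an estimated correlation), with ATF3 at -1.22 ± 0.07, SLC7A11 at -1.15 ± 0.05 and ASNS at -0.83 ± 0.05. Histone mRNAs (1 of 24 up, 19 down, 1 and 20 adjusted over the list alone, camera adjusted p = 0.000632, adjusted p = 0.411 with an estimated correlation) and G1/S genes (2 of 29 up, 15 down, 2 and 15 adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.380 with an estimated correlation) were lower too, as were G2/M genes (2 of 28 up, 16 down, 2 and 16 adjusted over the list alone, camera adjusted p = 0.00293, adjusted p = 0.500 with an estimated correlation). The survivin gene BIRC5 changed by -0.85 ± 0.06 and CCNB1 by -0.44 ± 0.06. Fibroblast markers were higher (4 of 5 up, 0 down, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0274, adjusted p = 0.238 with an estimated correlation), with FAP at 1.05 ± 0.07 and DCN at 1.00 ± 0.07. Cytokines did not pass camera (adjusted p = 0.0573), but passed with the replicate block (adjusted p = 0.0460), preranked (adjusted p = 0.0270) and on recovered counts (adjusted p = 0.0477). Their adjusted p was 0.506 with an estimated correlation, and 5 of 22 rose and 12 fell, with IL6 at -1.89 ± 0.07, CCL20 at -1.58 ± 0.07, CSF1 at 1.38 ± 0.06 and IL1B at 1.30 ± 0.08. Genes described as repressed by PRC2 (12 of 25 up, 6 down) did not pass either (adjusted p = 0.0845), but were higher preranked (adjusted p = 0.0163) and on recovered counts (adjusted p = 0.0213). Their adjusted p with an estimated correlation was 0.238. Among them WNT5A (1.33 ± 0.06), TIMP2 (1.21 ± 0.07) and SFRP1 (1.06 ± 0.06), which binds WNT ligands, rose. NF-kB feedback genes (11 of 29 up, 9 down) included ICAM1 (0.75 ± 0.06), and epithelial genes (7 of 20 up, 9 down) included EPCAM (-2.16 ± 0.07) and were lower in preranked camera alone (adjusted p = 0.0475, adjusted p = 0.649 with an estimated correlation). The 3 haematopoietic markers tested rose, as in MDA-MB-231 (CD68, CSF1R at 0.58 ± 0.06 and CD14 at 0.57 ± 0.07). The other lists did not pass: subunits and kinases (1 of 14 up, 6 down), PRC2 members (3 of 13 up, 7 down; 6 of 12 down without EZH2), survival (2 of 6 up, 1 down), pro-apoptotic (8 of 18 up, 4 down), hypoxia (6 of 20 up, 6 down) and Notch genes (6 of 11 up, 3 down). Median, mean and test differed in sign for pro-apoptotic and hypoxia genes, which did not pass.

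Limma called 3631 genes up and 3532 down in SUM149, 822 and 380 of them by at least 1.5-fold. Falls outnumbered rises with median centring (3454 up, 3792 down), quantile normalisation (3195, 3816) and the stricter filter (2224, 2697). Among genes with a mean at least 3 above the lowest value, the largest rises were CDH11 (2.09 ± 0.07, adjusted p = 3.3e-10), COL5A1, TFPI2 (1.78 ± 0.06), the metallothionein MT1E (1.76 ± 0.09) and APAF1 (1.75 ± 0.07). After EZH2, the largest falls among them were CNOT6 (-1.64 ± 0.06, adjusted p = 2.9e-10), PLS1 (-1.45 ± 0.06), C8orf33 (-1.44 ± 0.05) and CBX1 (-1.31 ± 0.05). EPCAM and IL6, under that level, fell by more than CNOT6, and CCL20, also under it, by more than PLS1.

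**Figure D2:**
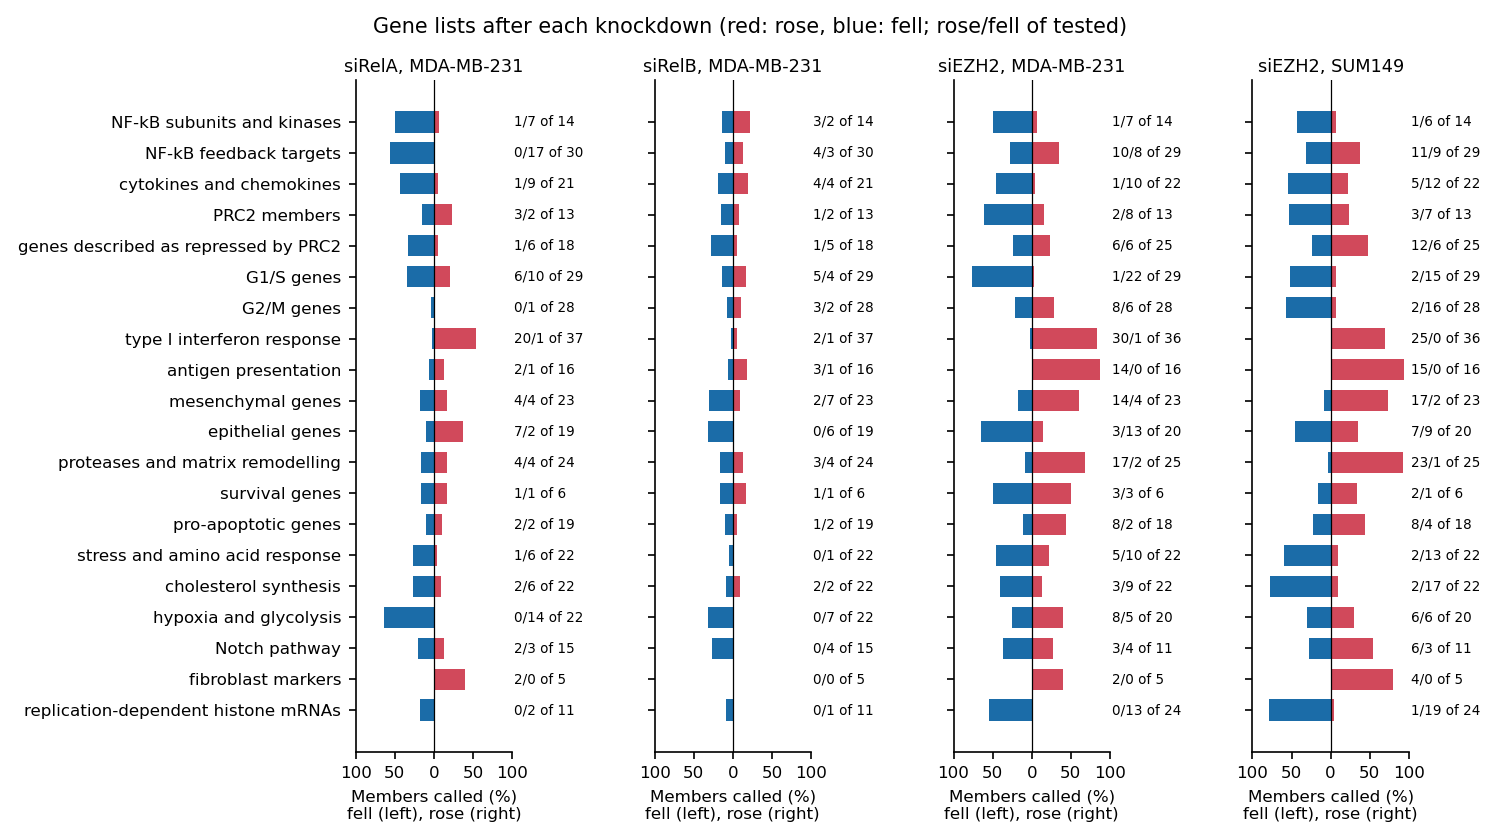
Percent of tested members of each fixed list that rose (red, right) or fell (blue, left) in each of the 4 knockdown comparisons, with the numbers that rose, fell and were tested beside the bars. Interferon genes rose in 20 of 37 cases under siRelA and in 30 and 25 of 36 under siEZH2 in MDA-MB-231 and SUM149, and hypoxia and glycolysis genes fell in 14 and 7 of 22 cases under siRelA and siRelB.

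The effects of siEZH2 in the lines overlapped. Limma called 2463 genes up and 2323 down in both lines, 4786 in all, against 1068 and 959 for independent calls, and 195 in opposite directions. HIPK3 (1.85 and 1.49), WDFY1 (1.62 and 1.67) and CDH11 rose in both, and CNOT6, CBX1 (-1.38 and -1.31) and SLC7A11 fell in both. The effect differed between the lines for 2662 genes, 1381 higher in SUM149 and 1281 lower. On recovered counts 1323 were higher and 717 lower, and of the 2662 calls 1709 were kept and 6 reversed. Among the largest differences were FMN1 (1.56 ± 0.11, -0.65 in MDA-MB-231 and 0.91 in SUM149), FAM102B (1.54 ± 0.09), PLAT, the tissue plasminogen activator (-1.73 ± 0.08, 1.91 and 0.18), PTGS2, cyclooxygenase 2 (-1.24 ± 0.08), NRG1 (-1.21 ± 0.10) and CLU (-1.18 ± 0.11). ANPEP also differed (1.54 ± 0.10), but it was near the floor in MDA-MB-231 and on recovered counts its difference was 0.17 and did not pass. The fall of EZH2 itself was smaller in SUM149 (difference 0.51 ± 0.10, limma adjusted p = 0.0035), and so was that of RELB (0.52 ± 0.11, limma adjusted p = 0.0044). The count of 2662 fell to 1611 and 1683 without MDA-MB-231 control replicate 1 and 2, and to 1772 without SUM149 siEZH2 replicate 2.

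Camera called 7 lists in this test of the difference, and with an estimated correlation camera called 0 of 20 lists, with 2 at an unadjusted p under 0.05. Mesenchymal genes (13 of 23 higher in SUM149, 3 lower, camera adjusted p = 0.000245) and proteases (15 of 25 higher, 6 lower, camera adjusted p = 0.000736) differed, with adjusted p = 0.367 and adjusted p = 0.386 with an estimated correlation. G1/S genes (8 of 29 higher, 0 lower) and G2/M genes (0 of 28 higher, 13 lower) each had camera adjusted p = 6.4e-05, with adjusted p = 0.367 and adjusted p = 0.386 with an estimated correlation. Cholesterol genes were lower in 8 of 22 cases and higher in 0 (camera adjusted p = 0.00814, adjusted p = 0.386 with an estimated correlation), and genes described as repressed by PRC2 higher in 11 of 25 and lower in 4 (camera adjusted p = 0.0275, adjusted p = 0.367 with an estimated correlation; adjusted p = 0.0555 on recovered counts). Interferon genes were lower in 12 of 36 cases and higher in 3 (camera adjusted p = 0.00828, adjusted p = 0.386 with an estimated correlation), but on recovered counts the direction turned and the list did not pass (adjusted p = 0.283). Stress genes, lower in SUM149 (adjusted p = 0.0439), and Notch genes, higher (adjusted p = 0.0124), passed on recovered counts alone. They had adjusted p = 0.386 and adjusted p = 0.472 with an estimated correlation. Adjusted over the list alone, the members higher and lower were 14 and 3 (mesenchymal), 16 and 6 (proteases), 10 and 0 (G1/S), 0 and 15 (G2/M), 0 and 10 (cholesterol), 11 and 5 (repressed by PRC2) and 4 and 13 (interferon).

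**Figure D3:**
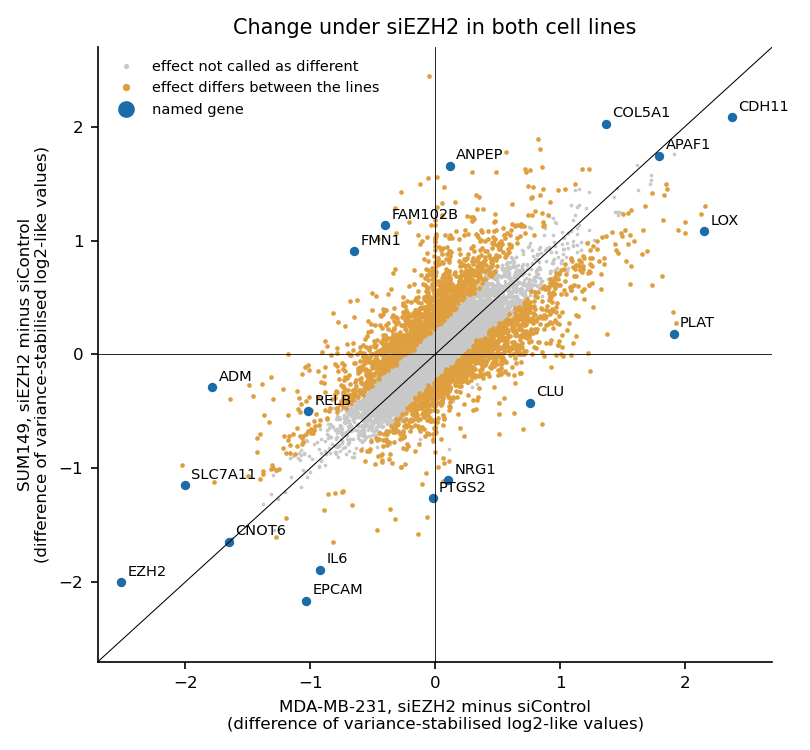
Change under siEZH2 in MDA-MB-231 (x axis) against SUM149 (y axis) on the deposited log2-like scale; orange points differed between the lines by the interaction test, blue points are named genes and the line marks equal change. FMN1 lies above the line and PLAT under it.

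Setting the experiments side by side asks which genes EZH2 shares with each NF-kB subunit in MDA-MB-231, over the 11630 genes tested in both. siEZH2 and siRelA called 657 genes up and 682 down together, against 395 and 433 for independent calls (odds ratios 2.65 and 2.30, Fisher exact p = 1.5e-58 and p = 2.6e-48 over genes, which are not independent replicates); 593 went in opposite directions, against 835. PRLR (1.24 and 2.78), COL5A1 and IFIT3 rose in both, and CDK2 (-0.97 and -1.44), PFKFB3 and ODC1 (-0.79 and -1.06) fell in both. siEZH2 and siRelB shared 760 genes in the same direction against 779 for independent calls and 996 in opposite directions against 792, with odds ratios of 1.06 for rises and 0.894 for falls (Fisher exact p = 0.409 and p = 0.0666). The shortfall of shared falls passed with the replicate block (odds ratio 0.861, Fisher exact p = 0.0168) and with calls at adjusted p under 0.1 (odds ratio 0.890, Fisher exact p = 0.0303). DPY19L1 and PTX3 rose in both, and ITGA3 (-0.82 and -1.38) and CHMP3 (-0.85 and -1.43) fell in both. The Spearman correlation of the changes across genes was 0.222 for siEZH2 with siRelA and -0.0536 with siRelB. In all 4 knockdown comparisons 85 genes fell. That was against 73.2 if the siEZH2 calls were independent of those shared by siRelA and siRelB (Fisher exact p = 0.128). Among the 85 were SDC4, CCN1, CCND1 and RELB, which is itself the target of siRelB. RELB and CCND1 also carry CCAATAA, the 3′ UTR word most tied to falls under siEZH2. In all 4, 115 rose, against 73.0 (Fisher exact p = 1.1e-07), among them the cyclin-dependent kinase inhibitor CDKN1B, MMP14, TGFBI and IFI6. Library preparation and processing differed between the experiments.

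The control libraries of the lines give the background. CXCL1 was higher in SUM149 by 7.60 ± 0.05 (limma adjusted p = 1.9e-18), HIST1H1B by 7.46 ± 0.07, the BMP antagonist GREM1 by 6.71 ± 0.06 and HIST1H2AE by 6.26 ± 0.06, while ANKRD1 (-6.46 ± 0.07), FLNC (-5.74 ± 0.06) and ANXA6 (-5.26 ± 0.07) were lower. Interferon genes were lower in SUM149 in 28 of 36 cases and higher in 3 (28 and 3 adjusted over the list alone, camera adjusted p = 5.3e-06, adjusted p = 0.373 with an estimated correlation). Also lower was antigen presentation, with 13 of 16 lower and 3 higher (camera adjusted p = 0.0180, adjusted p = 0.712 with an estimated correlation). Higher in SUM149 were cytokines (15 of 22 higher, 5 lower, camera adjusted p = 0.00237), G2/M (23 of 28, 1 lower, camera adjusted p = 0.000280), histone mRNAs (15 of 24, 4 lower, camera adjusted p = 0.00657), cholesterol (15 of 22, 6 lower, camera adjusted p = 0.0294) and stress genes (15 of 22, 5 lower, camera adjusted p = 0.0458), each with adjusted p = 0.712 with an estimated correlation. Adjusted over the list alone, the numbers of members of these 6 lists higher and lower were as over all genes. In total 5104 of 12356 genes were higher and 5132 lower.

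Genes that fell were also described by sequence, by relating each change to every 7-base word in the 3′ UTRs. Under siRelA the word with the lowest z score was GCCTAGT (z = -16.9, lowest of 100 shuffles -4.68), found in 168 of the 552 genes that fell at least 1.5-fold (30.4%) and in 4.59% of the others. For siRelB it was ACAAGAA (z = -6.75, shuffles -5.62), in 220 of 731 such genes (30.1%) and 13.9% of the others. For siEZH2 it was CCAATAA in MDA-MB-231 (z = -13.5, shuffles -5.14), in 140 of 385 such genes (36.4%) and 11.1% of the others, and again in SUM149 (z = -9.24, shuffles -4.77), in 104 of 348 (29.9%) and 11.3%. Each word stood in the coding sequence of the targeted mRNA: GCCTAGT in exon 11 of RELA, on chromosome 11 at 65654523 to 65654529, ACAAGAA in exon 10 of RELB, on chromosome 19 at 45034259 to 45034265, and CCAATAA in exon 11 of EZH2, on chromosome 7 at 148817362 to 148817368. A further copy of ACAAGAA spanned exons 7 and 8 of RELB, and a further CCAATAA stood in exon 10 of EZH2. The other word below all shuffles for siRelB, GCGACCA (z = -6.03), also stood in the RELB mRNA. It was in 35 of the 731 genes that fell at least 1.5-fold (4.79%) and in 0.894% of the others. Its carriers changed by -0.36 on average and other genes by -0.02, against -0.16 and 0.00 for ACAAGAA. Of all 7-base words, 11.7% to 13.8% stood in the respective targeted mRNA. TMX3 and MCL1 under siRelA, ITGB8 and GALNT12 under siRelB and SLC7A11, ADM, CNOT6, CCND1 and IL6 under siEZH2 carried the lowest-z word in their 3′ UTR, as did the riser CHORDC1 under siRelB. Of the 17 NF-kB feedback genes that fell under siRelA 3 carried it, and of the 22 G1/S genes that fell under siEZH2 in MDA-MB-231 also 3. The share was larger for hypoxia and glycolysis genes that fell under siEZH2 in MDA-MB-231 (5 of 5), in SUM149 (3 of 6) and under siRelB (3 of 7), and for G2/M genes in MDA-MB-231 (3 of 6). The highest z among the words was 19.8 for AATACAA in MDA-MB-231 (shuffles 4.92), present in 353 of 733 genes that rose at least 1.5-fold (48.2%) and 21.8% of the others, and 13.3 for CAATACA in SUM149 (shuffles 4.70), present in 177 of 812 such genes (21.8%) and 7.77% of the others. For siRelA it was TGACTAA (z = 8.18, shuffles 4.80) and for siRelB the overlapping GACTAAA (z = 5.99, shuffles 4.74). CDH11, SFXN1, LRRC58 and MGAT2 carried AATACAA.

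**Figure D4:**
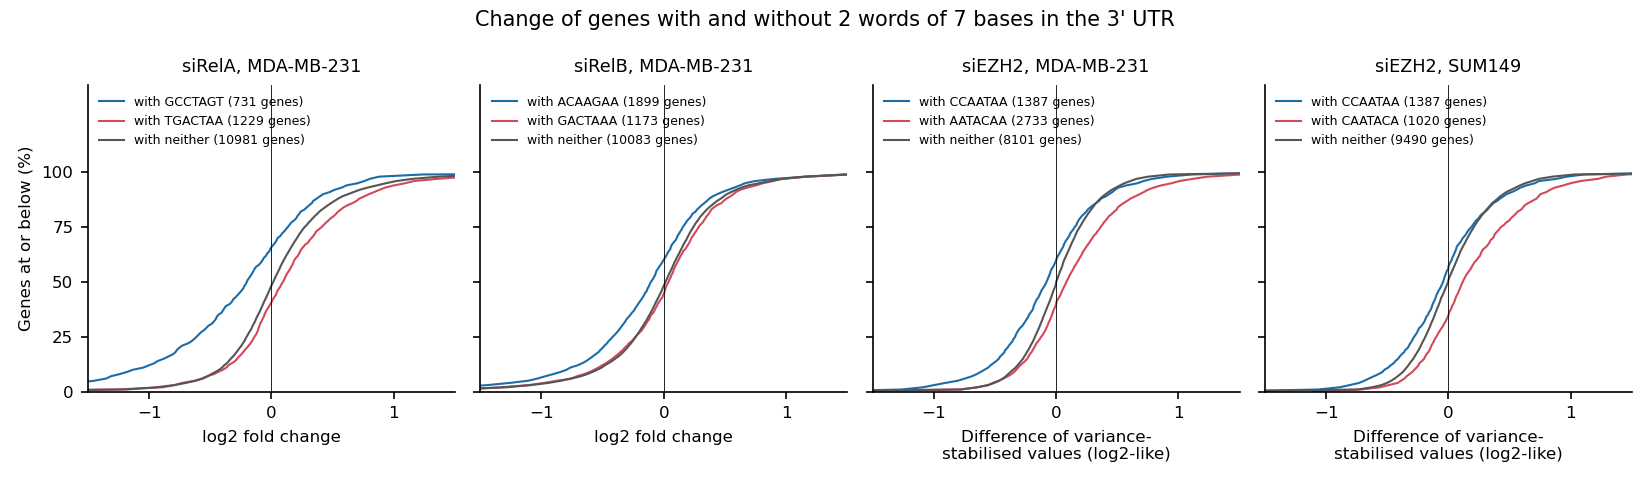
Cumulative percent of genes (y axis) against the change (x axis, log2 scale) for genes whose 3′ UTR holds the word with the lowest z (blue), the highest z (red) or neither (grey) in each of the 4 comparisons. The blue curves lie left of the grey ones and the red curves right. The words were chosen from these same changes, so the separation is not a further test. For siRelB the red shift was small (mean change 0.01 with GACTAAA, -0.03 without).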

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

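The tests of the words with the highest z score and the test of the RELB 8-base word were chosen after the result was seen; the tests of the words with the lowest z score and the interaction test were planned.

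The effect of siEZH2 differed between MDA-MB-231 and SUM149 for 2662 genes by the interaction test, and 195 genes were called in opposite directions in the lines. FMN1 (1.56), ANPEP (1.54) and FAM102B (1.54) changed more towards higher levels in SUM149, and PLAT (-1.73), PTGS2 (-1.24), NRG1 (-1.21) and CLU (-1.18) more towards lower levels. On recovered counts the difference for ANPEP was 0.17 and was not called. Camera on the interaction found the lists of genes repressed by PRC2 (median difference 0.0517), G1/S (0.18), mesenchymal genes (0.40) and proteases and matrix remodelling (0.38) higher in SUM149, and G2/M (-0.22), cholesterol synthesis (-0.16) and interferon response (-0.17) lower. With an estimated correlation these 7 had adjusted p from 0.367 to 0.386 and none was called, and on recovered counts the interferon difference turned direction and the list repressed by PRC2 had adjusted p = 0.0555. Of the 2662 calls 1709 were kept and 6 reversed on recovered counts. Among the genes in opposite directions were HAS2 (-0.32 in MDA-MB-231, 1.28 in SUM149), IL1A (-0.31, 1.07), ICAM1 (-0.32, 0.75), DUSP6 (-0.45, 1.01), CPA4 (0.86, -0.61) and JUN (0.63, -0.51). EZH2 itself fell less in SUM149, so a difference in knockdown depth is open and was not tested.

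In all 4 knockdown comparisons, the 3′ UTR word most tied to falls stood in the mRNA the siRNA was made against. A candidate explanation for part of the falls is off-target silencing through the siRNA seed, of which such a word can be a sign. Words tied to falls did not all stand there: TGCCTAG (z = -10.2 under siRelA), which overlaps GCCTAGT, was not in the RELA mRNA. The lowest z was -16.9 under siRelA, -6.75 under siRelB, -13.5 under siEZH2 in MDA-MB-231 and -9.24 in SUM149, each below every one of 100 shuffles, while 11.7% to 13.8% of all words stood in the targeted mRNA. The shuffles break every link between 3′ UTR sequence and change, so a word below them need not be a seed site. In SUM149 CAGTGGC lay below them too (z = -5.42), though the mean change was 0.03 for its carriers and 0.03 for other genes. Plain means were also compared, without the terms for length and GC content of the 3′ UTR, so small differences need not be specific to a word. GCCTAGT carriers differed from other genes by -0.34 under siRelA, -0.08 under siRelB and 0.01 and 0.03 under siEZH2 in the lines. CCAATAA carriers differed by -0.14 and -0.07 under siEZH2, 0.01 under siRelA and -0.08 under siRelB. Most genes that fell at least 1.5-fold lacked the lowest-z word, and 13 of 24 NF-kB feedback genes without that or the highest-z word fell under siRelA. Of the words below all shuffles, 4 of 13 under siRelA and 2 of 2 under siRelB stood in the targeted mRNA. Under siEZH2 these were 6 of 8 in MDA-MB-231 and 8 of 21 in SUM149. Examples were CGAGTGA in RELA (z = -6.27) and GCATCAT in EZH2 (z = -8.72 in MDA-MB-231). Several of the words counted share most of their bases, as CCAATAA and CCCAATA do, so they are not separate hits. Both siEZH2 comparisons also rest on a single siEZH2 treatment and do not count as independent. Genes with the other words in the targeted mRNA were not set apart, so lacking the lowest-z word does not mean lacking such a site. Changes that follow from the loss of RelA, RelB or EZH2 stay open beside off-target silencing.

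The words most tied to rises under siEZH2 were AATACAA in MDA-MB-231 (z = 19.8, in 48.2% of genes that rose at least 1.5-fold) and CAATACA in SUM149 (z = 13.3, in 21.8%). They were the highest of 48 and 25 words above all shuffles, and AATACAA had z = 12.8 in SUM149. Most such genes lacked the word named for their line, but the share with any of these words was not counted. A candidate explanation is that the control siRNA silenced genes with these sites, so that they stand higher in the siEZH2 libraries. By plain means, without the terms for length and GC content, AATACAA carriers in the first experiment differed from other genes by 0.00 under siRelA and -0.05 under siRelB. This stood against 0.14 and 0.12 under siEZH2 in the lines. CAATACA carriers differed by -0.05 and -0.09, against 0.21 and 0.18. Silencing by the control siRNA cannot be told apart from a change in a microRNA or RNA-binding protein after EZH2 loss. No control siRNA sequence is given, and each siEZH2 comparison has a single control treatment. The labels do not say whether both experiments used the same control siRNA. If they did, silencing by it would predict higher levels of the carriers under siRelA and siRelB too, which these means did not show. Of 30 interferon genes that rose in MDA-MB-231 6 carried the word, of 17 proteases and matrix genes 7 and of 8 pro-apoptotic genes 5.

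RELB fell under siEZH2 in both lines and carries CCCAATAA 25 bases from the end of its mRNA, within the 11-base stretch CTTCCCAATAA that the EZH2 mRNA holds in its coding sequence, and overlapping an AATAAA polyadenylation signal. Of 317 genes with the 8-base word 170 fell in MDA-MB-231 (53.6%, against 26.4% of others) and 144 in SUM149 (45.4%, against 28.3%). RELB stood at percentile 4.73 of these genes in MDA-MB-231 and 16.1 in SUM149. In MDA-MB-231 its fall was among their deepest: 15 of the 317, RELB included, stood at or below its -1.02. The ranking used the deposited scale, which understates falls of genes with few reads. It cannot decide whether RELB fell further than the site would bring. Silencing of RELB by the siRNA itself therefore cannot be told apart from an effect of EZH2 loss on RELB, because both predict the fall and the data hold a single siEZH2 treatment. An siRNA against another part of EZH2, or an inhibitor of its enzyme activity, would separate them.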

How the results depend on the processing

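The fits to recovered counts, the crossed replicate block and the lists without targeted genes were chosen after the result was seen; the gene lists, the naming rule and all other alternatives were set before the data were examined. Requiring a 1.5-fold change left 1341 calls for siRelA, 1324 for siRelB, 2383 for siRelA against siRelB, 1148 and 1202 for siEZH2 in MDA-MB-231 and SUM149, 473 for the difference between lines and 5125 between their controls, and 236, 570, 129 and 53 shared calls (siRelA with siRelB, siEZH2 in the lines, siEZH2 with siRelA, siEZH2 with siRelB); fewer calls follow from the added condition. At adjusted p under 0.1 siRelA and siRelB shared 1162. The stricter low-value filter left 1719 calls for the difference between lines and 6434 between controls, with fewer genes tested.

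With an estimated correlation, which leaves camera 3 or 4 residual degrees of freedom, it called 0 lists in each of the 7 comparisons. At an unadjusted p under 0.05 camera then found 5 for siRelA, 0 for siRelB and 4 for siRelA against siRelB. It found 2 and 4 for siEZH2 in MDA-MB-231 and SUM149, 2 for the difference and 1 for the controls. Leaving out 1 library each, siRelA ranged from 1624 (without control replicate 1; 1786 without control replicate 2) to 3287, siRelB from 1520 (without control replicate 2; 1754 without control replicate 1) to 3362, and the difference between lines from 1611 to 2532 (1611 and 1683 without MDA-MB-231 control replicate 1 and 2, 1772 without SUM149 siEZH2 replicate 2). A group left with 1 library was assumed to vary like the others. The targeted genes stayed called, with RELA from -3.83 to -3.62, RELB from -3.08 to -2.90 and EZH2 from -2.61 to -2.42 and from -2.08 to -1.93.

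Residuals of the same replicate number correlated at -0.0104, -0.0245 and 0.0476 in the first experiment. In the second they correlated at 0.0879 and -0.117 within the lines and from -0.207 to -0.00497 between them, so the numbers showed no positive pairing beyond 0.0879. With the replicate block the calls were 2958, 2828, 4680, 6937, 7132, 2571 and 9729 in the order above, and 724, 4727, 1293 and 729 shared. The crossed block gave 7278 in SUM149, recovered counts gave 7431, 7295, 2040 (1323 higher, 717 lower) and 11686, and the DESeq2 Wald test gave 2856, 2714 and 4229. Without RELA, RELB and EZH2 in the lists camera called 5 lists for siRelA, as subunits and kinases no longer passed. No named gene reversed under any alternative. Of 402 changes taken by the naming rule, leaving out at least 1 of the libraries ended the call of 39 and made a call of 21; the other alternatives ended calls for BCL2L11, NLRC5, U2AF1 and ANPEP and made calls for 18, among them AURKB under siRelA and NFKB1, JARID2 and IFI44 under siRelB. The cause was not tested. With the replicate block camera called 10 lists for siEZH2 in MDA-MB-231 and the cytokines in SUM149.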

Other observations

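The tests of shared calls among genes without the words and over 3 or 4 knockdowns were chosen after the result was seen.

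In MDA-MB-231, 140 genes fell and 163 rose under siEZH2, siRelA and siRelB alike. If the siEZH2 calls were independent of those that siRelA and siRelB, which share controls, had in common, 105 and 107 would do so (odds ratios 1.55 and 2.01, Fisher exact p = 8.7e-05 and p = 3.1e-10 over genes, which are not independent replicates). Genes whose 3′ UTR held neither the lowest-z nor the highest-z word of either comparison were also counted. Among these 6981 genes the overlap of siEZH2 with siRelA was beyond independent calls, with odds ratios of 2.80 for rises and 2.86 for falls. Counted the same way, siEZH2 with siRelB had odds ratios of 1.00 and 0.895, siRelA with siRelB 4.42 and 2.63, and siEZH2 in the lines 11.8 and 13.8. In all, 13 words lay below and 6 above every shuffle for siRelA, and 8 and 48 for siEZH2 in MDA-MB-231. Carriers of the other words were kept, so the remaining overlap cannot set such sites aside.

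No test identified the lines. Of 5796 transcripts with at least 1000 recovered counts in MDA-MB-231, 42 stood under 1% of that level in the SUM149 controls, which argues against an admixture of MDA-MB-231 material above that share. In the SUM149 controls FN1 was higher by 5.63, CDH2 by 3.98 and KRT5 by 3.21, and CD74 (-4.07), HLA-B (-3.61), KRT19 (-4.30) and DSP (-4.08) were lower than in MDA-MB-231. Mesenchymal and epithelial genes thus went both ways, with 10 of 23 higher and 12 lower and 8 of 20 higher and 11 lower, and neither list passed camera.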
